A study of Mus musculus with 4 samples.

How the data were processed

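RNA of ILC3 from the intestinal lamina propria of Bcl6 and Rorc double reporter mice was sequenced in 4 libraries, 2 labelled BCL6+ and 2 labelled BCL6-. Per the labels, total RNA was isolated with a column kit and the library was made by a service provider. Bowtie2, DESeq2 and the build mm10 are named without versions or roles, per the submitters' processing notes. The counting tool, the annotation, the strand setting and the rule by which genes were kept are not given in the sources used here.

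The deposited tables hold a count column and an FPKM column per gene symbol, per the file headers. The count values are whole numbers per gene that the authors did not scale. The FPKM values were made by the authors, and the ratio of count to FPKM between libraries was the same for every gene compared, as a length per gene and a factor per library would give. That factor did not follow the sum of counts. Single-transcript genes implied a total of 21833841 for replicate 2 labelled BCL6+, below its sum of counts, and totals of 23183622, 26138823 and 26171292 for the others, above theirs. Each table lists the same 13994 symbols, and no listed gene has fewer than 11 counts over the 4 libraries, so genes had been filtered before deposit. In the table of replicate 1 labelled BCL6+, 2 further columns equal the values of replicate 2 labelled BCL6+ and were not used. In 17 rows the symbol had been turned into a date, and those rows were kept under the text as listed. Of all symbols 13863 (99.1%) matched exactly 1 gene of GENCODE M21 on GRCm38, the assembly that mm10 names, and 27 matched more than 1. Positions were taken from that annotation.

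Totals of 22565173 and 23711538 counts for the libraries labelled BCL6+ and 25674038 and 25155000 for those labelled BCL6- set the depth. The floor of 3 counts that a count of 0 allows was applied per library. Floors and counting intervals (95%) cover counting error only, since reads without molecular identifiers are not independent molecules. Nothing in the labels says that replicates came from separate mice, so p-values of single genes measure only the spread between these libraries, which may be technical. List p-values likewise cannot stand for a spread between mice. With groups of 2 the design has few degrees of freedom.

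The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest without robust fitting, two-sided) in R 4.3.3 on counts scaled by TMM, with filterByExpr by group, which left 11006 genes, and Benjamini-Hochberg adjustment over these genes at a threshold of 0.05. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera sets list members against the other genes, so its p-values rest strongly on that correlation. The estimated correlation was far above the preset in the LTi-like list (0.117) and in the NCR+ ILC3 and group 1 ILC list (0.0984). The test covered the 23 of 27 lists with at least 5 tested members, of which 20 describe ILC or general cell programs and 3 other cell types. Counts of list members past the threshold were made over all genes and adjusted over the list alone. Fold values are ratios of mean CPM. Where a group had 0 counts the fold is a lower bound against the floor, and with 1 to 3 counts it is given with its counting interval. Neither covers the loss of a gene between libraries of the same label, which is described below. List medians use ratios with genes at 0 set to the floor. For 6 lists (common ILC regulators, Notch, circadian, immediate early, cell cycle and B cell markers) the median, the mean and the camera direction differed in sign.

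The comparison, the main test, the 27 lists, the named-gene rule and the alternative settings not marked as added were fixed before the data were examined. The rule names a panel of ILC genes whatever their values, then up to 14 genes per direction with the largest change among those past the threshold, with an average log2 CPM of at least 3, groups that do not overlap and a symbol that is not a predicted or Riken gene. If fewer than 5 pass, it takes the 10 smallest unadjusted p in each direction, which applied here. From each list it takes up to 4 members past the threshold, or else the 2 of largest mean level. Genes named outside the rule are said to have been chosen after their values were seen.

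Alternatives were a replicate block, RLE, upper-quartile and total-count scaling, no filter and a filter of 5 CPM in 2 libraries, robust fitting, an added log2 fold limit of 1, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with FPKM of at least 1 in 2 libraries, the former also without a filter, and each library left out in turn. For lists they were an estimated correlation, fry, the block, RLE scaling, both filters and each library left out. Totals implied by FPKM and filters at a mean of 20, 50 and 100 CPM were added after the data were seen. TMM factors were 1.02 and 0.918 for the libraries labelled BCL6+ and 1.02 and 1.05 for those labelled BCL6-. They raised and lowered the same libraries as the totals implied by FPKM, so that alternative lies close to the main scaling. Counts of list members without replicate 2 labelled BCL6+, also added, can by construction only hold or increase and are not given.

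The scripts were tested on simulated counts with the means and library sizes of these libraries and 200 changed genes. These were drawn from the genes tested at a mean of 10 CPM or more, so the recovery does not cover genes of lower level. At a dispersion of 0.05, edgeR recovered 13% of genes changed 2-fold and 99.5% of those changed 4-fold (11006 genes). At the dispersion estimated from these libraries (median 1.61) it recovered 0% at 2-fold (11004 genes), 2% at 4-fold and 57% at 16-fold (11001 genes each) and 83% at 64-fold (11004 genes). DESeq2 recovered 3, 14.5, 66 and 92% at these sizes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.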

Results

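The series measured RNA from group 3 innate lymphoid cells (ILC3), lymphocytes of mucosal tissue that depend on the transcription factor RORγt and make interleukin-22. The cells came from the lamina propria of the whole intestine of mice on the B6 background that carried a red fluorescent reporter at Bcl6 and a green fluorescent reporter at Rorc, the gene for RORγt. Bcl6 encodes a transcriptional repressor known from germinal centre B cells and follicular helper T cells. The 4 bulk RNA-seq libraries comprised 2 of ILC3 labelled BCL6+ and 2 of ILC3 labelled BCL6-. The series concerns the role of Bcl6 in keeping the identity of CCR6+ ILC3, and the comparison here asks which transcripts differ between the 2 labelled populations. Total counts were 22565173 and 23711538 in the libraries labelled BCL6+ and 25674038 and 25155000 in those labelled BCL6-. Of the 13994 genes listed, 18.9 and 23.5% had 0 counts in the libraries labelled BCL6+ and 16.2 and 21.9% in those labelled BCL6-. A count of 0 allowed up to 3 counts, or 0.114 to 0.138 CPM, the scaled count of a gene relative to the library total. Values below are CPM scaled by TMM, with n = 2 in each group.

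Bcl6, the gene of the labels, did not follow the labels on average. It lies on chromosome 16 from 23965052 to 23988852 on the minus strand (GRCm38, GENCODE M21, as for all positions below) and reached 17.1 and 20.5 CPM in the libraries labelled BCL6+ against 15.5 and 43.7 CPM in those labelled BCL6-. The log2 fold change was -0.65 (SE 1.07, 95% interval -3.50 to 2.19, adjusted p = 0.980), and without replicate 2 labelled BCL6- it was 0.28. Every direction below therefore rests on the labels as given and is stated for the libraries labelled BCL6+ against those labelled BCL6-. Rorc, the other reporter gene (chromosome 3, 94372794 to 94398276, plus strand), stood at 269 ± 20.03 CPM (SD) in the libraries labelled BCL6+ and 368 ± 71.4 CPM in those labelled BCL6- (adjusted p = 0.867).

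In the libraries labelled BCL6+, genes of CCR6+ lymphoid tissue inducer (LTi) cells such as Ccr6 and Cxcr5 were higher and genes of cytotoxic lymphocytes such as Nkg7 and Fasl lower. Ccr6, a chemokine receptor of LTi-like ILC3 (chromosome 17, 8236043 to 8257141, plus strand), had 125 and 66.9 CPM against 0 and 0.038 CPM, a ratio of 5037 with a counting interval of 910 to 200365. Cxcr5, the receptor for CXCL13 (chromosome 9, 44511787 to 44561877, minus strand), had 219 ± 51.8 CPM against 0.229 ± 0.270 CPM. In the other direction, Nkg7, a component of cytotoxic granules (chromosome 7, 43437073 to 43438249, plus strand), had 0 and 0.231 CPM in the libraries labelled BCL6+ against 2782 and 2741 CPM in those labelled BCL6-. Fasl, which encodes the death ligand, had 0 counts in both libraries labelled BCL6+ and 710 ± 12.0 CPM in those labelled BCL6-, at least 5265-fold lower.

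None of these differences passed the adjusted threshold. Of 11006 genes tested with edgeR's quasi-likelihood test, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the smallest was 0.163. At an unadjusted p under 0.05 there were 1171 genes, 462 higher and 709 lower in the libraries labelled BCL6+. That excess of lower genes turned to an excess of higher genes without replicate 1 or without replicate 2 labelled BCL6-. Those fits keep 1 library labelled BCL6- and take the spread from the libraries labelled BCL6+ alone. DESeq2 called 642 genes (260 higher and 382 lower), limma-voom called 0 and limma-trend on log2(FPKM + 1) called 6. In simulated data with the dispersion of these libraries DESeq2 made 249 to 358 false calls and edgeR 1 to 17, and edgeR had been set as the main test. A filter at a mean of 50 CPM, chosen after the data were seen, left 3177 genes and 37 edgeR calls, 10 higher and 27 lower. All 37 were also called by DESeq2, which used the same libraries and called many more genes, so the overlap is no separate support.

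The 10 genes with the smallest unadjusted p in each direction, none past the adjusted threshold, included receptors, transporters and cytokines. Hmgn3, which encodes a nucleosome-binding protein, was 152-fold higher (438 ± 7.55 against 2.88 ± 0.563 CPM, log2 fold change 7.25 with SE 0.44). Receptor genes on the higher side were Ramp1, a partner of the CGRP receptor, with 207 ± 15.8 CPM against 0 counts (at least 1809-fold higher), Vipr2, a receptor for vasoactive intestinal peptide, with 147 ± 37.7 CPM, and Ret, the receptor tyrosine kinase, with 102 ± 46.2 CPM. Vipr2 and Ret each had 1 count over both libraries labelled BCL6-, which gave counting intervals for the ratio of 1375 to 302732 and of 948 to 208683. Serpine2, a protease inhibitor, had 84.3 ± 30.5 CPM against 0.019 CPM. The cytokine gene Il17f had 221 and 894 CPM against 0 counts, at least 4866-fold higher. Slc6a13, a GABA transporter gene, was 12.5-fold higher and Nmrk1, a nicotinamide riboside kinase gene, 6.80-fold higher.

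On the lower side Klrc1, which encodes an NKG2 receptor and shares sequence with its paralogs, had 0.023 CPM against 381 ± 19.8 CPM. Slc6a20a, an amino acid transporter gene, and Smim3 had 0 counts in both libraries labelled BCL6+ and were at least 3036-fold and at least 1288-fold lower. Plek and Abi3bp had 0.068 CPM each against 124 ± 21.2 and 123 ± 44.4 CPM. Klrb1c, which encodes NK1.1 (chromosome 6, 128778485 to 128789215, minus strand), was 30.7-fold lower in the libraries labelled BCL6+ (35.8 ± 12.2 against 1097 ± 87.5 CPM). Ifng, the gene for interferon gamma, was 38.1-fold lower (11.5 ± 3.195 against 440 ± 116 CPM) and Ctsw, a cathepsin gene of cytotoxic cells, 19.8-fold lower. The adjusted p of these 10 genes in each direction lay between 0.163 and 0.371 in edgeR's quasi-likelihood test.

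**Figure D1:**
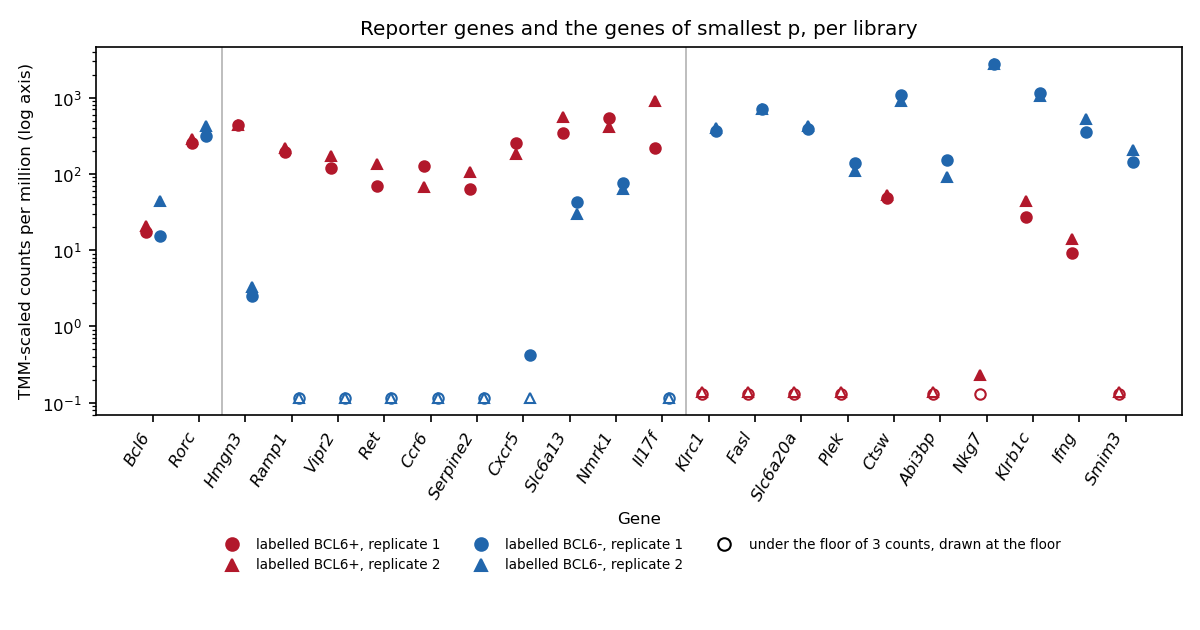
TMM-scaled CPM on a log axis for the reporter genes Bcl6 and Rorc and for the 10 genes of smallest p in each direction; each point is a library, colour gives the label, shape the replicate, and open symbols stand for libraries under 3 counts, drawn at the floor. Fasl sits at 719 and 702 CPM in the libraries labelled BCL6- and at the floor in those labelled BCL6+, whereas Bcl6 overlaps between the labels.

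LTi-like genes were higher as a group in the libraries labelled BCL6+. Of the 20 tested members of the LTi-like list, 15 were higher in both libraries labelled BCL6+ than in either labelled BCL6-, 2 were lower and 3 overlapped, with a median log2 ratio of 2.43. Nrp1, which encodes neuropilin 1 of LTi cells, had 59.0 ± 31.4 CPM against 0.115 ± 0.162 CPM. Cd4 had 10.6 ± 5.90 CPM against 0 counts, at least 92.8-fold higher by counting error alone. That bound is weak for a low gene. In the libraries labelled BCL6-, 21.5 and 31.3% of genes at 2 to 10 CPM in the other library of that label were at 0. Of the receptors for cytokines that activate ILC3, Il1r1 had 281 and 312 CPM against 60.7 and 2.37 CPM, and Il23r 599 and 542 CPM against 131 and 319 CPM. Tnfsf11, Lta and Tnfrsf11a, chosen after their values were seen, belong to the lymphotoxin and RANK pathways of tissue inducer cells. Tnfsf11 was 7.27-fold higher, Lta had 345 and 270 CPM against 109 and 43.7 CPM, and Tnfrsf11a had 29.1 ± 20.01 CPM against 0 counts. Of the members with the highest levels, Gpr183, an oxysterol receptor gene, was 2.06-fold higher, and Tmem176b overlapped at 1316 and 2920 CPM against 1348 and 1388 CPM, with a log2 fold change of -0.055 without replicate 2 labelled BCL6+. Zbtb16, the gene for PLZF, had 0 counts except for 4.02 CPM in replicate 1 labelled BCL6- and was not tested. The 2 lower members were Rorc and Ikzf3, the gene for Aiolos, named after its values were seen, which had 52.7 and 17.6 CPM against 249 and 263 CPM. Limma's camera with a preset correlation gave the list an adjusted p of 3.5e-08, and the call was lost at an adjusted p = 0.546 with an estimated correlation. Over all genes tested 0 members passed, and adjusted over the list alone 6 were higher (Ccr6, Cxcr5, Il17f, Nrp1, Tnfrsf11a and Tnfsf11) and Ikzf3 was lower. In the same libraries labelled BCL6+ the share of mitochondrially encoded genes was 3.68 and 6.34%, against 2.28 and 2.46%, and 8 of 13 T cell markers were lower (camera adjusted p = 0.0282, but adjusted p = 0.719 with an estimated correlation). Ribosomal protein genes took 7.43 and 14% of counts against 5.85 and 5.93%. Of 7 tested myeloid markers 4 were higher and 0 lower, and all 3 tested erythroid markers were higher.

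NCR+ ILC3 and group 1 ILC genes were lower as a group in the libraries labelled BCL6+. Of 33 tested members 31 were lower in both libraries, 0 were higher and 2 overlapped, with a median log2 ratio of -4.30. Ncr1, which encodes the receptor NKp46 (chromosome 7, 4337724 to 4345164, plus strand), had 169 and 373 CPM against 1398 and 1348 CPM, a 5.06-fold lower mean. Tbx21, the gene for the transcription factor T-bet, had 0 and 13.9 CPM against 80.2 and 92.1 CPM. Cxcr6, a chemokine receptor gene of NCR+ ILC3, was 2.58-fold lower, and Ccl4, a chemokine gene, had 0 and 26.1 CPM against 3876 and 4192 CPM. Several genes chosen after their values were seen went the same way. The cytotoxic genes Gzma and Prf1 and the receptor gene Il12rb2 had 0 counts in both libraries labelled BCL6+, and were at least 590.5-fold, at least 643-fold and at least 645-fold lower. The chemokine genes Xcl1 and Ccl3 had 11.3 and 67.1 CPM against 1946 and 1820 CPM and 13.6 and 52.8 CPM against 938 and 1102 CPM. Granzyme, killer lectin-like receptor and chemokine genes have close paralogs, so their single values are uncertain. Camera gave the list an adjusted p of 1.15e-15, and the call was lost at an adjusted p = 0.546 with an estimated correlation. Over all genes tested 0 members passed, and adjusted over the list alone 19 were lower. In the same libraries 8 of 13 T cell markers were lower (camera adjusted p = 0.0282, but adjusted p = 0.719 with an estimated correlation), and the mitochondrial share was higher.

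Cytokine genes of ILC3 were higher in the libraries labelled BCL6+ where they differed. Il22 (chromosome 10, 118204942 to 118210047, plus strand), the cytokine gene that defines ILC3 function in the gut, had 19253 and 15324 CPM against 4472 and 1814 CPM, a 5.50-fold higher mean. Ltb, which encodes lymphotoxin beta, was 1.94-fold higher, and Csf2, the gene for GM-CSF, overlapped at 630 ± 59.99 against 746 ± 238 CPM. Il17a had 0 and 26.9 CPM against 0 counts and was not tested. Of the 10 tested members of the effector cytokine list 5 were higher, 0 lower and 5 overlapped. Of these members 6 are also in another list. The higher members Il17f, Lta, Ltb and Tnfsf11 are in the LTi-like list too, so the 2 results are not separate. Camera gave an adjusted p of 0.0256, and the call was lost at an adjusted p = 0.719 with an estimated correlation. Over all genes tested 0 members passed, and adjusted over the list alone 3 were higher (Il17f, Il22 and Tnfsf11). The call for ILC3 effector cytokines was also lost without replicate 1 labelled BCL6+ (adjusted p = 0.0646), replicate 2 labelled BCL6+ (0.08) or replicate 2 labelled BCL6- (0.0755). The libraries labelled BCL6+ also had the higher mitochondrial share (3.68 and 6.34% against 2.28 and 2.46%), the higher ribosomal protein share (7.43 and 14% against 5.85 and 5.93%) and lower values of 8 of 13 T cell markers (camera adjusted p = 0.0282, but adjusted p = 0.719 with an estimated correlation).

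Genes of group 2 ILC and of follicular helper T cells went in different directions. Arg1, which encodes arginase 1, was 6.22-fold higher (500 ± 38.8 against 80.5 ± 42.9 CPM), and Gata3 overlapped at 79.8 ± 48.7 against 143 ± 57.3 CPM. Areg, Klrg1 and Calca, chosen after their values were seen, had 0 counts in both libraries labelled BCL6+, and Calca was at least 754-fold lower. Areg had only 7.57 and 23.6 CPM and Klrg1 11.2 and 21.3 CPM in the libraries labelled BCL6-, so their absence is weak. In the libraries labelled BCL6+, 23 and 31.9% of genes at 2 to 10 CPM in the other library of that label were at 0. At 10 to 50 CPM these shares were 11.7 and 15.1%. Of 11 tested group 2 members 3 were higher and 3 lower (camera adjusted p = 0.668, and adjusted over the list alone Arg1 and Ccr8 higher and Areg, Calca and Klrg1 lower). Of 8 tested members of the follicular helper T cell list 4 were higher and 3 lower (camera adjusted p = 0.273, and adjusted over the list alone Cxcr5, Pdcd1 and Tcf7 higher and Icos and Maf lower). Tcf7, the gene for TCF-1, was 3.17-fold higher, and Icos, a costimulatory receptor gene, 2.35-fold lower. Pdcd1, the gene for PD-1, chosen after its values were seen, had 8.19 and 12.7 CPM against 0 counts. Its absence is weak too, as in the libraries labelled BCL6- the shares at 0 were 21.5 and 31.3% at 2 to 10 CPM. They were 7.1 and 12% at 10 to 50 CPM.

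Genes reported as repressed by BCL6 did not move together. Of 29 tested members 13 were lower, 8 higher and 8 overlapped, with a median log2 ratio of -0.50 and a camera adjusted p of 0.319. Over all genes tested 0 passed, and adjusted over the list alone 4 were lower (Ccl3, Ccnd2, Prdm1 and Socs2). Prdm1, the gene for BLIMP1, had 0.044 and 0 CPM against 72.1 and 20.5 CPM, a ratio of 2114 with a counting interval of 369 to 81316. Socs2, Ccnd2 and Myc were chosen after their values were seen. Socs2 was 9.003-fold and Ccnd2 4.03-fold lower, and Myc had 1.27 and 0 CPM against 67.5 and 99.8 CPM. Cd69, an early activation receptor gene, was 2.99-fold higher, and Id2, which encodes a regulator required by all ILC, overlapped at 3967 ± 609 against 3280 ± 386 CPM.

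Common ILC regulators went in both directions. Il7r, the receptor gene for interleukin-7, was 1.36-fold higher and Kit 1.43-fold higher. Ahr, the gene for the aryl hydrocarbon receptor, was 2.96-fold lower and Maf, chosen after its values were seen, 2.27-fold lower. Il2ra overlapped at 292 ± 55.6 against 250 ± 24.4 CPM. Of 24 tested members 8 were higher, 9 lower and 7 overlapped (camera adjusted p = 0.918). In the Notch pathway list 2 of 10 members were higher, Notch2 among them at 1.80-fold, and 2 lower (camera adjusted p = 0.776). In the aryl hydrocarbon receptor target list 3 of 9 members were higher and 4 lower (camera adjusted p = 0.941), with Tiparp 1.35-fold lower. Adjusted over the list alone, 0 members passed in each of these 3 lists.

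Receptors for migration and adhesion differed in both directions. Ccr9, a gut-homing receptor gene, had 2.08 ± 2.08 CPM against 486 ± 138 CPM, and Ccr5 and Ccr2 had 0 counts in both libraries labelled BCL6+. Itga4, an integrin gene, had 159 and 161 CPM against 4.74 and 17.4 CPM, and Itgb7, the gene for its partner chain, was 3.86-fold lower. These 5 genes were chosen after their values were seen. Of 19 tested members of the migration list 7 were higher, 10 lower and 2 overlapped (camera adjusted p = 0.830, and adjusted over the list alone 5 higher and 6 lower). Among checkpoint and costimulatory receptors 2 of 13 members were higher and 9 lower, with Cd160 2.06-fold lower (camera adjusted p = 0.175, and adjusted over the list alone Pdcd1 higher and Cd244a, Ctla4, Icos, Klrg1 and Tnfrsf18 lower, some of them named after their values were seen).

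Interferon-stimulated genes were lower as a group in the libraries labelled BCL6+. Irf7, a regulator of type I interferon, had 6.70 and 39.7 CPM against 412 and 521 CPM, and Igtp, a GTPase gene induced by interferon gamma, was 5.04-fold lower. Irf9 and Stat1, chosen after their values were seen, were 12.2-fold and 4.46-fold lower, whereas Bst2, chosen likewise, was 2.78-fold higher. Of 25 tested members 14 were lower, 3 higher and 8 overlapped, with a median log2 ratio of -1.47. Camera gave an adjusted p of 0.00341, and the call was lost at an adjusted p = 0.546 with an estimated correlation. Over all genes tested 0 members passed, and adjusted over the list alone Igtp and Irf9 were lower. The call was also lost without replicate 1 labelled BCL6+ (adjusted p = 0.053). In the same libraries labelled BCL6+, the mitochondrially encoded share was higher, at 3.68 and 6.34% against 2.28 and 2.46%, and 8 of 13 T cell markers were lower. The call for T cell markers was likewise lost with an estimated correlation (adjusted p = 0.719) and without replicate 1 labelled BCL6+ (adjusted p = 0.389).

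Antigen presentation, clock, TGF-beta and immediate early genes showed no common direction. Of the genes of MHC class II chains, H2-Aa had 276 and 618 CPM against 71.1 and 0.191 CPM and H2-Ab1 75.5 and 36.3 CPM against 34.3 and 23.5 CPM, and Ctss overlapped at 265 ± 94.5 against 179 ± 30.3 CPM. Of 10 tested MHC class II members 4 were higher and 3 lower (camera adjusted p = 0.746). Of 18 circadian genes 7 were higher and 3 lower (camera adjusted p = 0.668), with Bhlhe40 1.95-fold lower and Rora 1.28-fold higher. Of 12 TGF-beta response genes 4 were higher and 3 lower (camera adjusted p = 0.918). Rgs1 was 1.65-fold lower, and Tgif1 overlapped at 1147 and 209 against 923 and 775 CPM. Of 32 immediate early and dissociation genes 14 were higher and 6 lower (camera adjusted p = 0.553). Zfp36 had 7585 and 1323 CPM in the libraries labelled BCL6+ against 3818 and 3787 CPM, and Nfkbia had 4334 and 1306 CPM against 3719 and 3178 CPM. Adjusted over the list alone, the immediate early gene Dusp2 was lower and 0 passed in the 3 other lists.

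Mitochondrially encoded genes were higher in the libraries labelled BCL6+. Of 13 tested members 12 were higher and 1 overlapped, with a median log2 ratio of 1.38. These genes have nuclear copies of their sequence, so single values are uncertain. For example, mt-Cytb had 9539 and 15294 CPM against 4449 and 5152 CPM, and mt-Co1 had 7373 and 15509.9 CPM against 5543 and 5429 CPM. Camera gave an adjusted p of 4.16e-05, and the call was lost at an adjusted p = 0.719 with an estimated correlation. Adjusted over the list alone and over all genes 0 members passed. Ribosomal protein genes took 7.43 and 14% of counts in the libraries labelled BCL6+ and 5.85 and 5.93% in those labelled BCL6-.

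Genes of energy metabolism and the cell cycle were mixed. Of 46 nuclear oxidative phosphorylation genes 16 were higher and 8 lower (camera adjusted p = 0.243). Cox6a1 overlapped at 793 and 2151 CPM against 764 and 861 CPM, and Cox8a at 723 and 1450 CPM against 897 and 769 CPM. Of 18 glycolysis genes 4 were higher and 9 lower (camera adjusted p = 0.466). Hk2, a hexokinase gene, was 2.33-fold higher and Ldha, a lactate dehydrogenase gene, 1.75-fold lower. Of 19 cell cycle genes 5 were higher and 5 lower (camera adjusted p = 0.941), with Pcna 1.505-fold higher and Cenpa at 49.2 and 18.0 CPM against 125 and 101 CPM. Adjusted over the list alone, 0 members of these 3 lists passed.

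Among T cell markers in the libraries labelled BCL6+, 8 of 13 tested members were lower, 1 was higher and 4 overlapped. Camera gave an adjusted p of 0.0282, and the call was lost at an adjusted p = 0.719 with an estimated correlation. It was also lost without replicate 1 labelled BCL6+, without replicate 2 labelled BCL6- and under a filter of 5 CPM in 2 libraries. Adjusted over the list alone Lck and Trbc1 were lower, and 1 of the tested members is also in another list. Lck, a kinase gene also used by innate lymphocytes and named after its values were seen, was 11.9-fold lower. Constant-region genes of the T cell receptor share sequence and are uncertain. Trbc2 overlapped at 760 ± 351 against 1088 ± 250 CPM, and Tcrg-C1 at 792 ± 335 against 787 ± 55.2 CPM.

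Markers of other cell types were also measured. Myeloid markers took 0.362 and 0.559% of counts in the libraries labelled BCL6+ and 0.397 and 0.353% in those labelled BCL6-, where T cell markers took 0.14 and 0.232% against 0.372 and 0.348%. Of 7 tested myeloid markers 4 were higher and 0 lower (camera adjusted p = 0.131), with Cst3 at 627 and 1306 CPM against 534 and 441 CPM and Fcer1g 1.35-fold higher. The others, chosen after their values were seen, were Lyz2, at 21.8 and 33.7 CPM against 0.115 and 0.305 CPM, and Zbtb46, at 19.9 and 23.7 CPM against 2.68 and 0.878 CPM. Of 6 tested B cell markers 2 were higher and 1 lower (camera adjusted p = 0.918, and adjusted over the list alone Ighm lower). The immunoglobulin gene Ighm, uncertain as a multi-copy locus, was 4.83-fold lower, and Xbp1 was 1.46-fold higher. The remaining 4 lists had fewer than 5 tested members and no set test. Mast cell markers took 0.000771 to 0.0121% of counts, with Cpa3 at 3.83 ± 5.35 against 62.8 ± 67.1 CPM and Hdc at 6.14 ± 8.68 against 6.17 ± 0.901 CPM. Epithelial markers took 0.000286 to 0.00616% and had 0 tested members. Stromal markers took 0.00558 to 0.00999%, with Pecam1 at 62.9 ± 11.4 against 61.9 ± 12.2 CPM and Igfbp7 at 20.2 ± 16.2 against 3.71 ± 5.25 CPM. Erythroid markers took 4.67e-05 to 0.00134%, with Hbb-bs and Hba-a2, members of multi-copy families, at 4.82 ± 3.22 and 2.18 ± 1.03 CPM in the libraries labelled BCL6+ against 0.153 ± 0.216 and 0.0573 ± 0.0269 CPM. All 3 tested erythroid markers were higher in both libraries labelled BCL6+, and Hba-a2 passed when adjusted over the list alone.

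**Figure D2:**
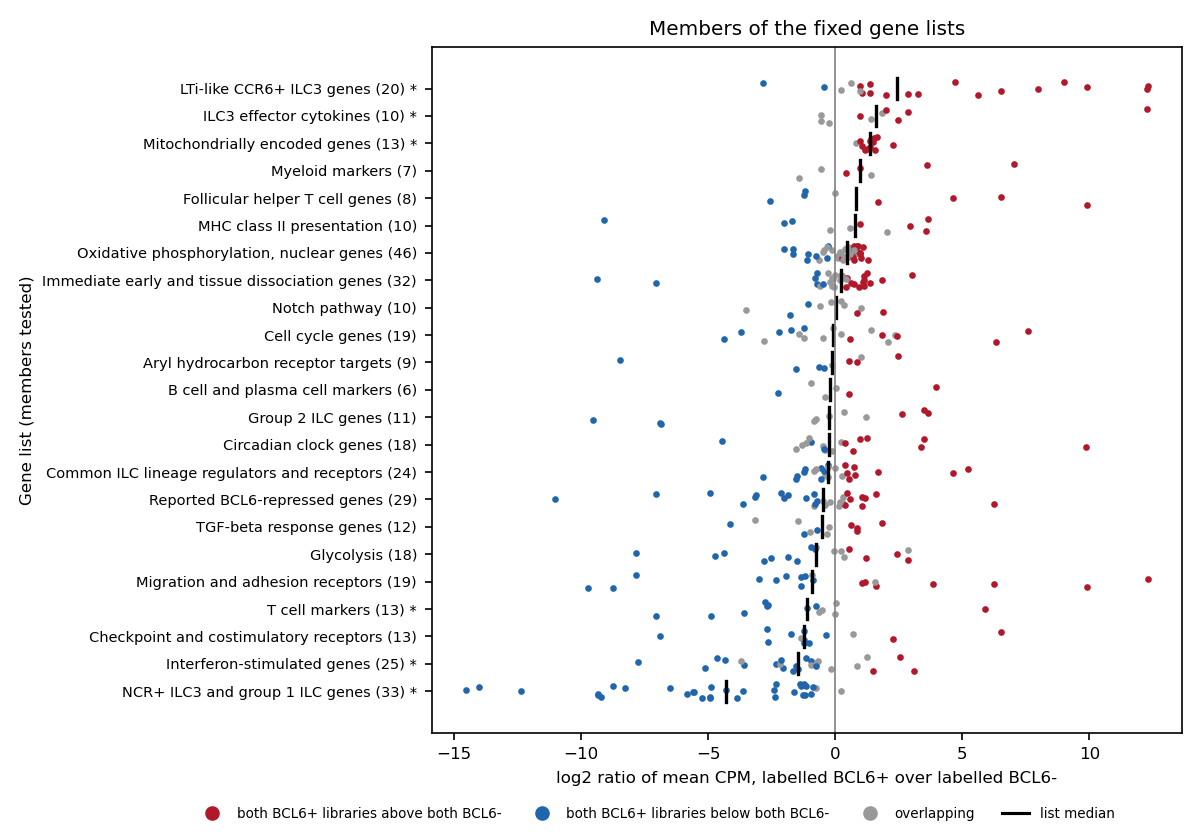
Log2 ratio of the mean CPM of the libraries labelled BCL6+ over those labelled BCL6- for each tested member of the 23 lists with a set test; red points are genes higher in both libraries labelled BCL6+, blue points are lower in both, grey points overlap, black bars are list medians, genes at 0 in a group are set at the floor, and an asterisk marks lists called by camera with a preset correlation. The NCR+ ILC3 and group 1 ILC list has its median at -4.30 and the LTi-like list at 2.43.

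Libraries of each label differed widely among themselves. On the first principal component of the 500 most variable genes, with 56.3% of the variance, the libraries labelled BCL6+ scored -47.9 and -87.3 and those labelled BCL6- 59.8 and 75.4. Across 11006 genes, which are not independent replicates, the Pearson correlation of log2 CPM was 0.589 between the libraries labelled BCL6+, 0.665 between those labelled BCL6-, and 0.499 to 0.589 across labels. The matching Spearman correlations were 0.699, 0.791 and 0.625 to 0.733. Genes with both libraries labelled BCL6+ above both labelled BCL6- numbered 2264 (20.6%) and those below 2609 (23.7%), where chance gives 16.7% in each direction. The common dispersion in edgeR was 1.48. Many genes with a clear level in a library were at 0 in the other of the same label, most often replicate 2 labelled BCL6+, in which 31.9% of genes at 2 to 10 CPM in the partner were at 0.

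**Figure D3:**
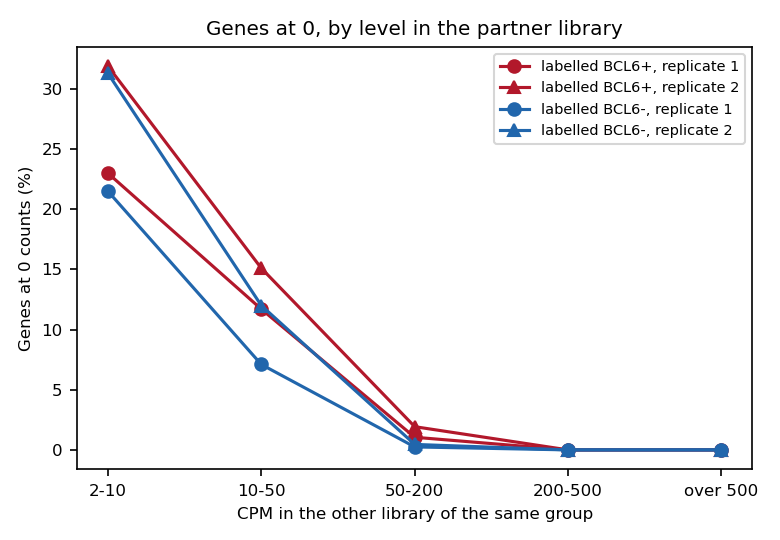
Percent of genes at 0 counts in a library, by their CPM in the other library of the same label; each line is a library, colour gives the label and shape the replicate. The share falls from 21.5 to 31.9% at 2 to 10 CPM to 0% above 200 CPM.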

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

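The filters by mean CPM and the totals implied by FPKM were chosen only after the data were seen. The edgeR count of 0 genes held under the block (0 calls, 490 at an unadjusted p), RLE, upper-quartile and total-count scaling, no filter, the 5 CPM filter, robust fitting, the fold limit, totals implied by FPKM, limma-voom and limma-trend on log2(FPKM + 0.1). Fits without a library keep 1 library in a label and take the spread from the other label alone. They cannot show whether the count is stable. The count became 642 with DESeq2, 6 with limma-trend on log2(FPKM + 1), 5 without its filter, and 24, 37 and 57 at a mean of 20, 50 and 100 CPM, with 23 and 28 of the 37 shared. The cause was not tested, except that the CPM filters test 5554, 3177 and 1742 genes at dispersions of 0.584, 0.266 and 0.173. The unadjusted count of 1171 became 490, 527, 447 and 320 under the block and these filters, and 336 to 2202 without a library: 2202 without replicate 1 labelled BCL6+, 514 and 336 without replicate 1 and 2 labelled BCL6-, where more genes were higher than lower. The deviations of same-numbered libraries correlated at 0.00751 across genes. This cannot tell whether numbers mark shared mice, because many genes fell to 0 in single libraries. Upper-quartile scaling moved the median log2 fold change from -0.06 to 0.10.

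Bcl6 kept a negative log2 fold change in all alternatives that gave a value except without replicate 2 labelled BCL6- (range without a library -1.22 to 0.28). The first component took 45.8% with all genes. Called lists of ILC or general cell programs numbered 5: LTi-like, NCR+ ILC3 and group 1 ILC, effector cytokine, interferon-stimulated and mitochondrially encoded genes. With an estimated correlation or fry they numbered 0. Without replicate 1 labelled BCL6+ the calls of effector cytokines and interferon-stimulated genes were lost. Without replicate 2 of either label the call of effector cytokines was lost. Called marker lists numbered 1 (T cell markers), and 0 with an estimated correlation, fry or the 5 CPM filter. The T cell call was also lost without replicate 1 labelled BCL6+ or replicate 2 labelled BCL6-. Among named genes, 1784 values under settings that kept all libraries held direction and side of the threshold and 159 came to pass it.

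The following changed sign, none past the threshold. Log2 fold changes of Zfp36 were -0.26 with the block, -0.25 with limma-voom and -0.28 in all 3 limma-trend fits. Those of Tcrg-C1 were -0.057 with the block, -0.11 with total counts, -0.060 with limma-voom, -0.0743, -0.0745 and -0.0743 with limma-trend, -0.0070 with FPKM-implied totals and -0.038 at a mean of 100 CPM. Hdc had 0.0491 with RLE, 0.22 with upper-quartile scaling, 0.033 with the 5 CPM filter and 0.0492 with DESeq2. Pecam1 had -0.080 with total counts. Trac had 0.0162 with RLE, 0.15 with upper-quartile scaling, 0.032 with the 5 CPM filter, 0.01625 with DESeq2, and 0.042 and 0.0037 at a mean of 20 and 50 CPM. Actb had 0.017 with upper-quartile scaling. Adjusted p-values of lists that turned were 0.354 (MHC class II, fry), 0.983, 0.882 and 0.714 (aryl hydrocarbon receptor targets with the block, no filter and 50 CPM), 0.822 (circadian, 50 CPM), 0.487 (immediate early, fry), 0.963, 0.716 and 0.732 (cell cycle with fry, no filter and the 5 CPM filter), 0.732 (TGF-beta, 5 CPM filter) and 0.983 (B cell, block).

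Without a library, results of which at least 1 value turned ranged as follows. Log2 fold changes lay from -0.055 to 1.15 for Tmem176b, -0.54 to 0.12 for Csf2, -1.47 to 0.996 for Zfp36, -1.35 to 0.33 for Nfkbia, -0.035 to 1.46 for Cox6a1, -0.20 to 0.85 for Cox8a, -1.97 to 0.43 for Tgif1, -0.50 to 0.44 for Tcrg-C1, -10.27 to 1.04 for Hdc, -0.17 to 0.25 for Pecam1, -0.23 to 0.22 for Trac, -8.63 to 0.39 for Cd3d and -1.28 to 0.54 for Actb. Adjusted p-values lay from 0.382 to 0.974 for Group 2 ILC genes, 0.738 to 0.974 for Common ILC lineage regulators and receptors, 0.265 to 0.974 for Notch pathway, 0.762 to 0.974 for Aryl hydrocarbon receptor targets, 0.729 to 0.974 for Cell cycle genes, 0.666 to 0.974 for TGF-beta response genes and 0.783 to 0.974 for B cell and plasma cell markers. The cause of these changes was not tested. Depth limits single low genes to the floor of 3 counts.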

Other observations

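The tests of depth, of an exchange of libraries, of the spread of Bcl6 and of Rorc were chosen only after the results were seen, as was the rule that a bound must be missed by more than the spread within labels, applied to T cell genes and Rorc.

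The genes named here were chosen after their values were seen, and all but Actb had no overlap between the labels, none past the adjusted threshold. Tgm2, which encodes transglutaminase 2, had 45.0 and 37.2 CPM in the libraries labelled BCL6+ against 0.038 and 0 CPM. Ptges, the gene for a prostaglandin E synthase, had 63.4 and 140 CPM against 1.03 and 0 CPM, and Dll1, which encodes a Notch ligand, had 17.2 and 101 CPM against 0.6501 and 0 CPM. Slamf7, a receptor gene of cytotoxic lymphocytes, had 0 counts in both libraries labelled BCL6+ against 242 and 103 CPM. Egr1, of the immediate early list, was 7.98-fold higher, at 3960 and 1065 CPM against 322 and 307 CPM. Actb, a cytoskeletal gene, overlapped between the labels, at 12434 and 3395 CPM in the libraries labelled BCL6+ against 9610 and 7478 CPM, its lowest level being in the library with the highest mitochondrial share.

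Summed over the 4 libraries, a gene was at 0 while the other library of the same label had 50 or more counts in 4206 of 36460 cases (11.5%), so a gene can count more than once. Depth is argued against, since Poisson sampling of reads predicted 8.38e-10 such cases. Exon length and GC content are argued against as the main account, since the probability that a lost gene exceeded a kept gene of like level stayed near 0.5. For length it was 0.442 and 0.454 in the libraries labelled BCL6+ and 0.467 and 0.457 in those labelled BCL6-. Lost genes were thus slightly shorter in each library. For GC content it lay from 0.48 to 0.544. Few RNA molecules captured per library may account for the pattern, as the share at 0 fell at each level to 0% at 200 to 500 CPM and stayed at 0% above 500 CPM, but the bound set in advance asked for a further fall at that last step, which a share of 0 cannot give, so it stays open. No biological explanation was tested.

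Bcl6 was not higher in the libraries labelled BCL6+. The LTi-like genes without Rorc kept a median log2 ratio of at least 2.21 in all 4 pairs of a library labelled BCL6+ and one labelled BCL6-. This argues against an exchange of 1 library labelled BCL6+ with 1 labelled BCL6- only if these genes follow the true status of the cells, which was not tested. The ratio cannot speak to an exchange of both. The spread between libraries could hide a higher level, because the upper 95% bound of the log2 fold change was 2.19, above a 2-fold difference. A reporter that outlasts the transcript was not tested.

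Cytotoxic and group 1 ILC genes were higher in the libraries labelled BCL6-. Carried over T cells cannot be told apart from a difference among ILC3. The summed CPM of 6 T cell genes in the lower library labelled BCL6- was 1.40 times that in the higher library labelled BCL6+. That was below the bound of 2, which the wording set in advance counted against T cells. It was below by less than the spread (SD of log2 0.601), so the rule added later left T cells open. Most of the sum came from Trbc1 and Trbc2, whose single values are uncertain. Trac had 75.0 and 76.8 CPM in the libraries labelled BCL6- against 88.6 and 62.6 CPM in those labelled BCL6+. Cd3d had 1.57 and 2.37 against 0 and 2.49 CPM, and Cd3e 0 and 21.9 CPM against 0 counts. Trac, Cd3d, Cd3e and Trbc2 overlapped between the labels, whereas Trbc1 and Cd3g were higher in both libraries labelled BCL6-. A replacement of ILC3 by cells without Rorc, which needed a log2 ratio of Rorc of -1 or less in the libraries labelled BCL6- over those labelled BCL6+, is argued against, since the ratio was at least 0.166 in all 4 pairs, above that bound by more than the spread of 0.282, but a smaller admixture of such cells stays open, which a gate on the Rorc reporter, not stated in the labels, would remove. The real split parted 1150 genes by at least 4 times and the other splits 705 and 626. Only the real split itself, 1 of 3, reached that count, too few splits for a share under 0.05. With edgeR each split gave 0 adjusted calls, and 1171 genes against 453 and 398 had an unadjusted p under 0.05. Under the later filter at a mean of 50 CPM, calls numbered 37 against 0 and 0. The other splits mix the labels within each side, which adds to their spread. A biological difference between the labelled populations remains among the open explanations.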
